A study of Homo sapiens with 12 samples.

How the data were processed

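Gene expression was measured by sequencing of polyadenylated RNA in 12 libraries of homogenized human lung parenchyma, prepared with a kit that keeps the strand of the transcript, per the labels' protocols. The lungs were donor lungs kept on ex vivo lung perfusion, in which a lung is ventilated and perfused outside the body on a circuit. Per the labels, 6 libraries were taken before lipopolysaccharide at 0 h and 6 at 4 h. Of the latter, 3 were labelled as having had no intervention and 3 as treated with BC1215. Per the labels' protocols, E. coli endotoxin at 5 mg/kg ideal body weight entered the pulmonary arterial side of the circuit at 1 h. BC1215 or its saline vehicle was instilled through a bronchoscope at 2 h. Groups were taken from the labels. The labels do not tie a library to a donor, so it is not known here which libraries before and after lipopolysaccharide share a lung. No group at 4 h without lipopolysaccharide was analysed here, so each comparison with the earlier libraries holds the endotoxin and the time on the circuit together.

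Trimmomatic 0.36, TopHat2 2.1.1, Cufflinks 2.2.1 and the human build GRCh37 are named in the submitters' processing notes. The layout of the tables, with a tracking identifier, a condition, a replicate number, fragments and a status, is that of Cuffdiff, a program of the Cufflinks suite, per the file headers. The gene annotation, the strand setting of the counting and the read length are not given in the sources used here. The deposited estimated counts are fragments per locus and library before scaling, per the file headers. They covered 60151 loci, and 22848 of these were at 0 in every library. Of the 721812 values, 100 were not whole within a tolerance of 1e-06, and all were rounded to whole numbers before testing. The deposited signal values are the same fragments divided by a size factor per library, per the file headers and the values. The authors' signal per condition equalled the mean of the scaled fragments over that condition's libraries to within a relative difference of 7.6e-06. The authors' FPKM values are fragments scaled by locus length and library size, per the file headers. The table numbers libraries within a condition from 0, and the labels number them from 1. Libraries are named below by their group and the table's own number, which only names them.

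The loci carry only identifiers that Cufflinks assigns anew in each run, and the files do not pair them with gene names or coordinates. Of these identifiers, 3 also stand as symbols and 10 as synonyms of long noncoding RNAs in a RefSeq gene table. Those names come from other transcript catalogues with their own numbering, so they were not taken as matches. No gene was named from an identifier. For this reason 49 gene lists written before the data were examined, the cell type markers among them and the genes chosen to be named could not be applied. Sex-linked genes, which were to be left out, could not be recognized and stayed in the counts of loci. The rule for named genes took, in each comparison, loci at an adjusted p under 0.05 with at least 2 CPM on average in a group and no overlap of the libraries, and the 12 with the largest change in each direction. It also left out identifiers without a symbol. The 4 loci named below were therefore chosen after their values were seen. They are the 2 called in the control arm and the 2 that fell most by the numerical part of the rule with both arms together.

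The status column marked 123 values as FAIL and 2 as HIDATA, in 68 loci altogether. In the 1 locus with HIDATA, 2 libraries were listed at 0 while it was among the 3 most abundant loci in each of the other libraries, so those values were treated as missing. All 68 loci were left out, a choice made after the data were examined. Fragments in the remaining loci were tested with edgeR 4.0.16 under R 4.3.3. Low-count loci were removed with filterByExpr by group, which left 20589 loci holding 97.7% of all fragments. Libraries were scaled by TMM. A negative binomial model with a term per group was fitted to all 12 libraries at once, so that the groups share an estimate of the spread, and contrasts were tested with the quasi-likelihood F test. The common dispersion was 0.178, a biological coefficient of variation of 0.422. P-values were adjusted by Benjamini-Hochberg over all loci in each of 4 contrasts, and a locus was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with standard errors from the same fit, and CPM values are TMM-scaled. Principal components were computed on log2 CPM with a prior count of 2. Single measures per library were compared by exact two-sided permutation tests. With 3 against 3 libraries such a test cannot give a p under 0.1.

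Depth ranged from 35898403 to 44740771 fragments per library. Each fit was tested on simulated counts for the 20589 loci, drawn with the means, dispersions and library sizes of the data and with 200 changed loci. Among loci changed 2-fold, 8.82% were recovered in the control arm, 11.8% in the BC1215 arm, 1.47% between the arms and 36.8% with both arms together. Among those changed 4-fold, the shares were 72.7%, 78.8%, 72.7% and 81.8% in the same order. Among those changed 8-fold they were 89.4%, 95.5%, 86.4% and 97.0%. The 200 changed loci comprised 68 at 2-fold, 66 at 4-fold and 66 at 8-fold. The simulated counts lacked the variation that real loci share, so these shares need not hold for the real libraries. In the real data the median 95% interval of a log2 fold change reached 0.74 on either side in each arm, 0.86 between the arms and 0.61 with both arms together.

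Alternatives fixed before the data were examined were RLE scaling, no low-count filter and a filter of at least 1 CPM in at least 3 libraries. Further ones were DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and on log2(FPKM + 0.1), a fit of only the groups compared, a fold threshold of 2, a replicate block and each library left out in turn. Alternatives added after seeing the data were loci of every status except the HIDATA locus, library totals in place of TMM, removal of each library's trend with locus length, limma voom with library weights and DESeq2 on the loci that passed the low-count filter of the reported fit. Relative locus length was taken as scaled fragments divided by FPKM. Other splits of the libraries into groups of the same sizes were refitted, 84 for each arm against the pre-LPS libraries, 10 between the arms and 100 drawn for both arms together, the real split among them. Because both arms are compared with the same pre-LPS libraries, 20 simulated data sets without any effect gave the agreement that shared controls alone produce. For loci picked in the BC1215 arm, 20 further simulated data sets had that arm changed as fitted at its 642 called loci and the control arm unchanged. All 20 divisions of the pre-LPS libraries into 3 and 3 were also refitted. These checks of picked loci were added after the calls were seen.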

Results

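Polyadenylated RNA of human lung tissue was sequenced before and after a challenge with lipopolysaccharide (LPS), the endotoxin of Gram-negative bacteria that activates innate immune cells through toll-like receptor 4. Donor lungs were kept on ex vivo lung perfusion. The 12 libraries comprised 6 taken at 0 h, before LPS, and 6 taken at 4 h, after LPS. Of the libraries at 4 h, 3 came from the control arm and 3 from the arm given BC1215, a small molecule that inhibits FBXO3, the substrate-binding subunit of a ubiquitin ligase. The stated purpose was to examine how tissue expression changed after LPS and how BC1215 altered that change. The labels name no donors, so the p-values below measure the spread between libraries, and any lung sampled both before and after LPS entered as separate libraries. Expression was counted over 20589 tested loci that carry Cufflinks identifiers only, and the files do not pair these with gene names. Results are therefore given for groups of loci and for 4 loci by identifier.

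The ranges of depth overlapped between groups. The 6 pre-LPS libraries held 35898403 to 44347669 fragments, the 3 control libraries 37280888 to 38898379 and the 3 BC1215 libraries 36379895 to 44740771. Loci with at least 10 fragments numbered 18888 to 19607 in the pre-LPS libraries, 18031 to 19184 in the control libraries and 19534 to 20070 in the BC1215 libraries. The arms did not overlap in this number (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give, and 0.4 after adjustment over 4 measures). The TMM factor averaged 1.07 before LPS and 0.941 after it (exact permutation p = 0.0498, and 0.199 after adjustment). Spearman correlations of log2 CPM across loci were 0.943 to 0.983 within groups and 0.914 to 0.981 between groups. No pair of libraries within a group looked like 1 library listed again (smallest chi-square per degree of freedom 80.7), which does not tell whether libraries share a lung. The main axis of variation, 32.1% of the variance, ran from -92.3 to 18.0 in the pre-LPS libraries and from -13.7 to 88.3 in the post-LPS libraries. This difference in means of 83.3 had an exact permutation p of 0.0152 (two-sided, n = 6 and n = 6), and 0.0608 after adjustment over 4 components. On the next axis, 20.2% of the variance, the BC1215 libraries lay between -76.5 and -26.1 and the control libraries between -4.39 and 77.4. The exact permutation p of 0.1 is the smallest that 3 against 3 libraries can give, and it was 0.4 after adjustment over the 4 components. The pre-LPS libraries alone ran from -31.0 to 69.1 on this axis. Differences between lungs and BC1215 cannot be told apart there, since the labels name no donors.

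**Figure D1:**
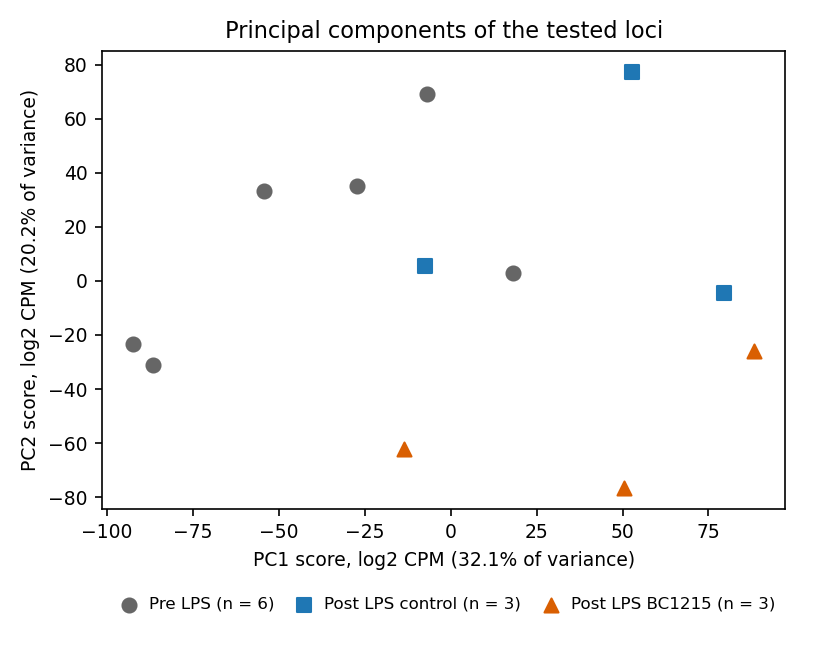
Scores of the 12 libraries on the first and second principal components of log2 CPM over the tested loci, with 32.1% and 20.2% of the variance on the axes and a point for each library. Of the 6 post-LPS libraries, 4 lie to the right of all pre-LPS libraries, the groups overlap between -13.7 and 18.0, and the BC1215 libraries lie below the control libraries. The pre-LPS libraries run from -31.0 to 69.1 on the second component.

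With both arms in a joint contrast, lung tissue at 4 h differed from tissue before LPS at 1449 loci, of which 902 were higher and 547 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 6 against 6 libraries). Fitted rises were larger than falls among the called loci. The median rise was 1.26 on the log2 scale (quartiles 0.93 and 1.81) and the median fall -0.83 (quartiles -1.05 and -0.67). At least a 2-fold change was fitted for 616 of the higher and 167 of the lower loci, and at least an 8-fold rise for 55. All 902 higher loci had fitted values above the pre-LPS level in the control arm and in the BC1215 arm, and all 547 lower loci had values below it in both, which the joint contrast favours. At 529 of the 1449 loci the post-LPS and pre-LPS libraries did not overlap. Over all tested loci this share was 3.42%, where chance gives 0.217%.

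With TMM scaling, rises were called at every level of abundance before LPS, and falls mostly at intermediate levels. The split over these levels was not repeated with other scalings. Of 4660 tested loci with a mean under 1 CPM before LPS, 233 rose, by a median of 2.16 on the log2 scale, and 24 fell. The low-count filter keeps such a locus where it is higher in another group, which favours rises among them, and a fall from so low a level is hard to detect. From 1 to 10 CPM, 154 of 5272 loci rose and 145 fell. From 10 to 100 CPM, 423 of 8762 loci rose, by a median of 0.98, and 373 fell, by a median of -0.74. At 100 CPM or more, 92 of 1895 loci rose and 5 fell. XLOC_033950 and XLOC_050004 had the largest falls among called loci with at least 2 CPM and separated libraries. XLOC_033950 went from 11.6 ± 5.18 CPM (SD, n = 6) before LPS to 1.85 ± 0.477 (SD, n = 3) in the control arm and 1.79 ± 0.50 (SD, n = 3) in the BC1215 arm. Its log2 fold change with both arms together was -2.68 (SE 0.366, edgeR adjusted p = 0.0279), and it was lower in 6 of 6 post-LPS libraries than in any pre-LPS library. XLOC_050004 stood at 2.95 ± 1.06 CPM (SD, n = 6) before LPS, 0.876 ± 0.305 (SD, n = 3) in the control arm and 0.549 ± 0.409 (SD, n = 3) in the BC1215 arm. Its log2 fold change was -2.08 (SE 0.410, edgeR adjusted p = 0.0326), again lower in 6 of 6 libraries. For both loci this separation was a condition of the pick and is no separate support.

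The number of calls lay at the edge of what the threshold admits, since the smallest adjusted p of any locus was 0.0279, while 6005 loci had an unadjusted p under 0.05. At that threshold 1029 would be expected from independent loci without effects, and other splits of the 12 libraries gave up to 4662. The number of calls fell to 0 without pre-LPS library 1, 3, 4 or 5, control library 2 or BC1215 library 1, to 30 without BC1215 library 0 and to 915 without control library 0, and it rose to 2646 without control library 1 and to 3187 without BC1215 library 2. In each of these fits every tested member of the 1449 loci kept its direction, and the largest unadjusted p among them was 0.0161, except for 0.136 without control library 2. The loci were picked on the same libraries, all but 1 of which each fit shares. Kept directions and small unadjusted p were therefore nearly fixed in advance and are no separate support. The balance of rises and falls followed the scaling: with library totals in place of TMM, under which the median log2 fold change of all loci was -0.211 against -0.023 with TMM, 641 loci were higher and 1214 lower. With each library's trend with locus length removed, 848 were higher and 996 lower. Over the alternative scalings, filters and libraries left out, the log2 fold changes were -2.88 to -2.49 for XLOC_033950, with edgeR adjusted p from 0.00204 to 0.0924, and -2.43 to -1.85 for XLOC_050004, with edgeR adjusted p from 0.0154 to 0.0931. With the replicate block, not among these, they were -2.559 for XLOC_033950 and -2.015 for XLOC_050004, each at an edgeR adjusted p of 0.4. DESeq2 called 3787 of 37175 loci, 2170 higher and 1617 lower, and 3818 among the loci that passed the low-count filter. Limma voom with library weights called 4722.

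**Figure D2:**
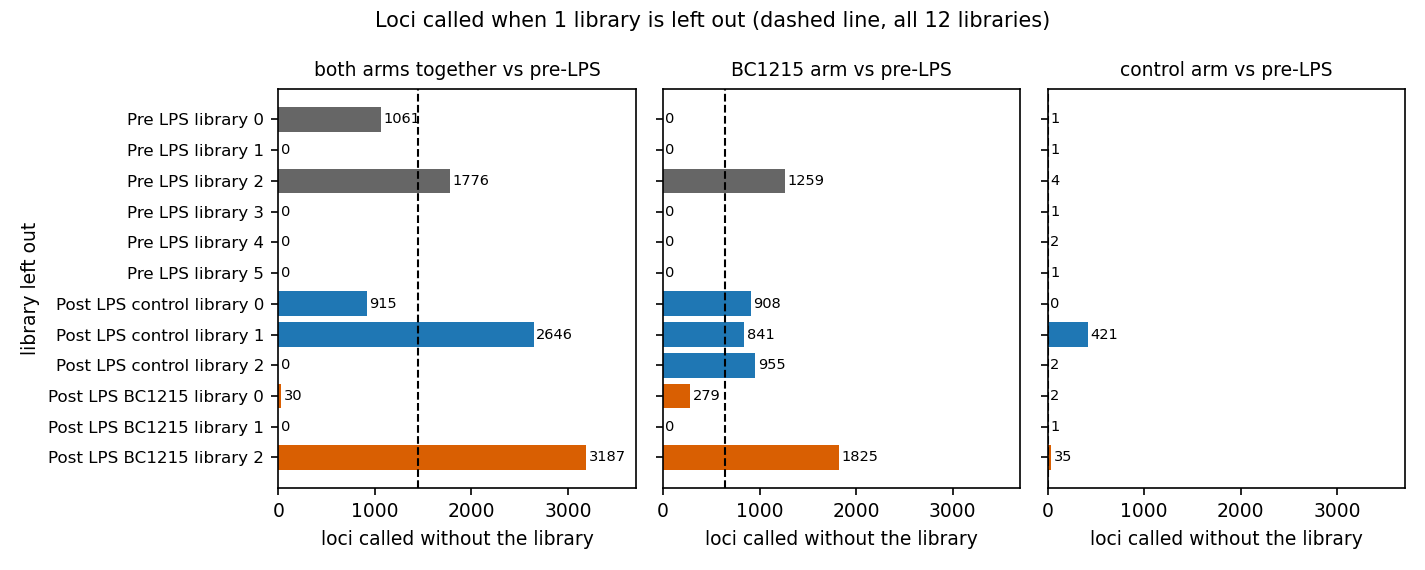
Loci called at an adjusted p under 0.05 when the library on the vertical axis is left out of the fit, with the count on the horizontal axis, for both arms together, the BC1215 arm and the control arm against the pre-LPS libraries. Bars take the colour of the group of the library left out and dashed lines mark the counts of 1449, 642 and 2 with all 12 libraries, and the counts run from 0 to 3187, 0 to 1825 and 0 to 421.

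In the control arm, which shows the change from 0 h to 4 h with LPS given at 1 h and without BC1215, 2 loci passed the test, and both were higher after LPS. XLOC_033855 rose from 1.66 ± 0.447 CPM (SD, n = 6) to 9.42 ± 1.59 CPM (SD, n = 3), a log2 fold change of 2.50 (SE 0.262, edgeR adjusted p = 0.00796). XLOC_029391 rose from 0.122 ± 0.104 CPM (SD, n = 6) to 4.39 ± 2.79 CPM (SD, n = 3), a log2 fold change of 5.16 (SE 0.633, edgeR adjusted p = 0.0223). For both loci each of 3 control libraries lay above all 6 pre-LPS libraries. At an unadjusted p under 0.05 there were 4423 loci, 2417 higher and 2006 lower, but 3 of 84 splits of the same 9 libraries, the real split included, gave as many, and the highest other gave 5071.

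The count in the control arm differed between methods. DESeq2 called 1621 of 37175 loci and 1731 among the loci that passed the low-count filter, the latter fit added after seeing the data. Without this filter edgeR called 22. The edgeR count was 421 without control library 1, 35 without BC1215 library 2, 4 without pre-LPS library 2, 1 without pre-LPS library 0, 1, 3 or 5 or BC1215 library 1, and 0 without control library 0. Over the alternative scalings, filters and libraries left out, XLOC_033855 had log2 fold changes of 2.26 to 2.61 with edgeR adjusted p from 0.00303 to 0.0659. XLOC_029391 had log2 fold changes of 4.60 to 5.68 with edgeR adjusted p from 0.00303 to 0.109. With the replicate block, not among these settings, XLOC_033855 had 2.18 and XLOC_029391 had 4.64, each at an edgeR adjusted p of 0.7.

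In the BC1215 arm, 642 loci differed from the pre-LPS libraries, 537 higher and 105 lower (edgeR quasi-likelihood test, adjusted p under 0.05, 3 against 6 libraries). Higher loci had a median log2 fold change of 1.86 (quartiles 1.31 and 2.63), and 104 of them rose at least 8-fold. Lower loci had a median of -1.01. Of the 537, 220 had been under 1 CPM before LPS, where the filter favours rises, and their median log2 fold change was 2.79. Both loci called in the control arm were also higher in this arm. XLOC_033855 reached 3.59 ± 0.523 CPM (SD, n = 3), a log2 fold change of 1.11 (SE 0.266, edgeR adjusted p = 0.0468), and XLOC_029391 reached 1.84 ± 0.761 CPM (SD, n = 3), a log2 fold change of 3.90 (SE 0.624, edgeR adjusted p = 0.0338). XLOC_033950 had a log2 fold change of -2.70 (SE 0.485, edgeR adjusted p = 0.0338) and XLOC_050004 of -2.42 (SE 0.547, edgeR adjusted p = 0.0424). In the control arm their log2 fold changes were -2.66 (SE 0.485, edgeR adjusted p = 0.0721) and -1.75 (SE 0.524, edgeR adjusted p = 0.115), which did not pass.

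The smallest adjusted p in the BC1215 arm was 0.0338, and 5147 loci had an unadjusted p under 0.05, against at most 5104 in other splits of the same libraries. The count of calls fell to 0 without pre-LPS library 0, 1, 3, 4 or 5 or BC1215 library 1 and to 279 without BC1215 library 0, and rose to 1259 without pre-LPS library 2 and to 1825 without BC1215 library 2. It was 2773 with DESeq2 (1697 higher and 1076 lower), 2756 with DESeq2 on the loci that passed the low-count filter (1627 higher and 1129 lower) and 345 with the stricter filter. Library totals gave 247, and a fit of only the groups compared gave 997. Limma voom with library weights called 5764, 3220 higher and 2544 lower, and weighted BC1215 library 1 at 3.45, against 0.495 and 0.858 for the others of its group. With the trend with locus length removed, the split was 419 higher and 233 lower.

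**Figure D3:**
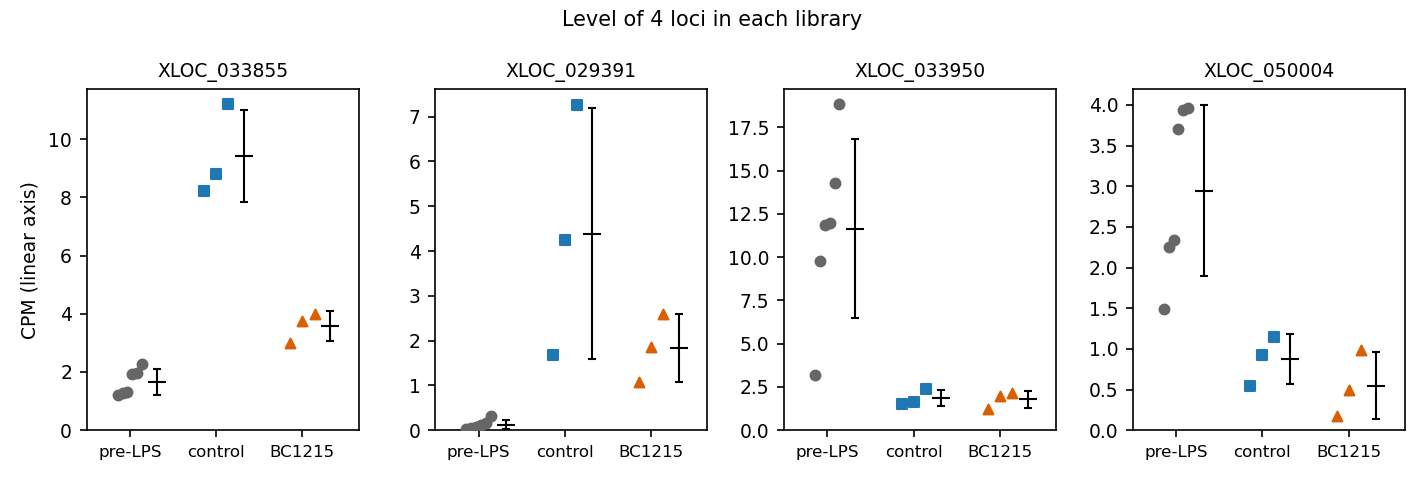
CPM of the 4 loci named in the text on linear axes from 0, with a point for each of the 6 pre-LPS, 3 control and 3 BC1215 libraries and, beside the points, the mean and SD of each group. XLOC_033855 and XLOC_029391 are higher and XLOC_033950 and XLOC_050004 lower in all 6 post-LPS libraries than in any of the 6 pre-LPS libraries. XLOC_033950 and XLOC_050004 were picked among loci with such separated libraries.

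The direct comparison of the arms at 4 h addresses the effect of BC1215 on tissue already exposed to LPS. No locus differed between the BC1215 and control arms by the edgeR quasi-likelihood test (3 against 3 libraries), and the smallest adjusted p was 0.603. At an unadjusted p under 0.05 there were 1683 loci, 957 higher and 726 lower in the BC1215 arm, while another split of the 6 libraries gave 3689. The arms also separated in the number of loci with at least 10 fragments, higher in each BC1215 library than in any control library. DESeq2 called 39 loci, 25 higher and 14 lower with BC1215, and 40 among the loci that passed the low-count filter, while limma on FPKM and limma voom called 0. The groups did not overlap at 12% of tested loci, where chance gives 10%. The median 95% interval reached 0.86 on either side of the fitted log2 difference, and in simulated data of this design 1.47% of loci changed 2-fold were recovered, so the absence of calls does not show that the arms were alike. XLOC_033855 was lower in the BC1215 arm than in the control arm in 3 of 3 libraries, with a log2 difference of -1.39 (95% interval -2.08 to -0.70, edgeR adjusted p = 0.603). It had been picked for its rise in the control libraries, which favours such a difference. For XLOC_029391 the difference was -1.25 (95% interval -2.74 to 0.23) and for XLOC_050004 it was -0.67 (95% interval -1.92 to 0.58).

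No difference between the arms was detected over the loci that rose or fell after LPS as groups. Of the 902 loci higher with both arms together, 36.1% were lower in the BC1215 arm than in the control arm, and the median difference was 0.20 on the log2 scale (exact permutation p = 0.6 over the arm labels, two-sided, smallest possible 0.1). Their median change from the pre-LPS libraries was 1.13 in the control arm and 1.35 in the BC1215 arm. Of the 547 lower loci, 47.9% were lower in the BC1215 arm, with median changes from the pre-LPS libraries of -0.86 and -0.81 in the control and BC1215 arms (exact permutation p = 1 for the median difference). Other divisions of the 6 post-LPS libraries gave shares from 5.99% to 94.0% for the 902 loci, a range that holds the value for the real arms. The share among the 902 loci was 49.9% without control library 1 and 16.5% without BC1215 library 2.

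Changes from the pre-LPS libraries were positively correlated between the arms. Across loci, which are not independent replicates, the Pearson correlation of the log2 changes was 0.605 and 73.0% had the same sign. Unchanged groups simulated against the same pre-LPS libraries gave 0.330 and 60.7%. The covariance was 0.318 against 0.076 in the simulation, a difference of 0.242. When the pre-LPS libraries were divided so that each arm had 3 of its own, the correlation averaged 0.427 over 20 divisions, with a range from 0.120 to 0.674, and the covariance averaged 0.244. Of the 642 loci called in the BC1215 arm, 620 had the same sign in the control arm, and 412 of these had an unadjusted p under 0.05 there. These loci were picked on the same pre-LPS libraries, so the values are set against simulated data in which the control arm was unchanged. There, of the 642 loci with the smallest p in the BC1215 arm, 57.1% had the same sign (53.9% to 60.0% over 20 simulations), against 96.6% observed, and 43.2 on average had an unadjusted p under 0.05. With 3 pre-LPS libraries for each arm, the share averaged 88.1% over 20 divisions, with a range from 57.5% to 96.6%. Both simulations drew counts from means, dispersions and library sizes, without the variation that real loci share. The narrow simulated range is therefore not that of real libraries without a change. The 537 higher loci had a median log2 fold change of 0.99 in the control arm. Both loci called in the control arm were among the 537.

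**Figure D4:**
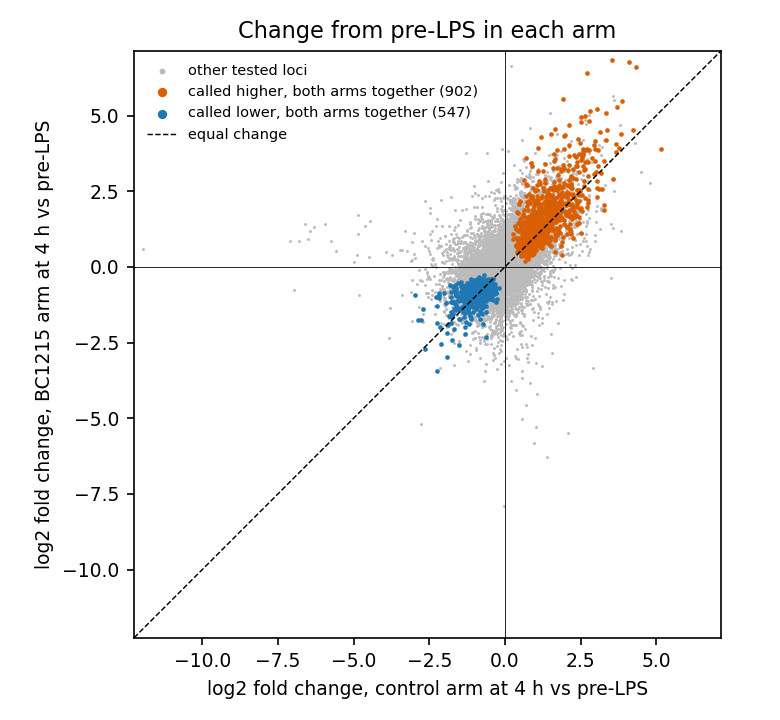
Log2 fold change from the pre-LPS libraries in the control arm, on the horizontal axis, and in the BC1215 arm, on the vertical axis, with a point for each of 20589 loci, loci called with both arms together coloured by direction and equal change as a dashed line. The 902 higher loci lie in the upper right and the 547 lower loci in the lower left, and part of the correlation of 0.605 comes from the shared pre-LPS libraries.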

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

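The removal of the trend with locus length, the use of library totals, the comparison of the arms at an unadjusted threshold and the reading of the direct test between the arms were tests chosen only after the result was seen.

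A signal outside the tested loci drew attention: 2.28% of all fragments lay in the 68 loci left out for their status. A locus among them held up to 2.06% of a library's fragments and was listed at 0 in 2 libraries, the same 2 in which it was marked HIDATA. In 9 checks of the pre-LPS libraries for a library far from the others, none passed the threshold, where chance gives about 1 in 20. The share of fragments in the left-out loci came closest: pre-LPS library 5, one of the 2 with this locus at 0, had 0.935% against 2.12% to 2.84%, a gap of 0.620 of the range. The share of this locus alone was not among the checks.

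The 1449 loci called with both arms together exceeded the highest count of the other splits, 374. Of the 100 splits drawn 1, the real split itself, called as many. This argues against chance only if the libraries within a group are independent. That is not known, because some libraries may share a lung, which the labels do not tell. A lung shared by a pre-LPS and a post-LPS library would place differences between lungs within the groups, not between them. The tables argue against a trend with locus length as the whole cause, because 94.0% of the calls kept their direction and stayed past the threshold once it was removed. They also argue against fragments drawn by the 10 most abundant loci, whose mean share differed by -0.638 percentage points after LPS with overlapping libraries, which moves other loci by 0.01 on the log2 scale. Scaling stays open for the balance of directions: library totals gave 1855 calls, 1163 of them among the 1449, but 1214 were then lower and 641 higher. The trend with locus length stays open for this balance too, since its removal gave 848 higher and 996 lower. A response of the tissue to LPS and 4 h on the circuit cannot be divided by this design, and no biological explanation beyond their sum was tested.

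More loci were called in the BC1215 arm, 642, than in the control arm, 2, while without control library 1 the counts were 841 and 421 and without BC1215 library 1 they were 0 and 1. Without pre-LPS library 0, 1, 3, 4 or 5 the BC1215 arm had 0 calls. The gap stayed without control library 0 (908 and 0), control library 2 (955 and 2) or pre-LPS library 2 (1259 and 4). It also stayed without BC1215 library 0 (279 and 2) or BC1215 library 2 (1825 and 35). At an unadjusted p under 0.05 the BC1215 arm had 1.16 times as many loci as the control arm, so the gap may come from single libraries and from a threshold that magnifies a small difference in evidence. A different response in the BC1215 arm stays open, since the direct test called 0 loci and cannot exclude smaller differences, with 1683 loci at an unadjusted p under 0.05 and 3689 in another split. Among 84 splits 1, the real split itself, called 642 or more and the highest other called 567. At an unadjusted p under 0.05 there were 5147 loci against at most 5104 in another split. The margin is narrow. It argues against chance only if the libraries within a group are independent, which the labels do not tell. For the control arm 8 of 84 splits called 2 or more and the highest called 305, so this count could not exclude chance. The 5 splits that called over 3 times as many may reflect a structure of the samples other than the groups, which was not tested. The count was 0 in 76 other splits. At an unadjusted p under 0.05, 3 of 84 splits, the real split included, gave as many as the 4423 loci of the control arm.

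Between the arms, the real split called 0 and the highest other split 0, with 10 of 10 splits as large, and 10 splits are too few for a share under 0.05.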

How the results depend on the processing

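Library totals, the removed trend with locus length, loci of every status, limma voom with library weights, DESeq2 on the filtered loci and the closest library of each post-LPS library were tests chosen only after the result was seen.

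Without a low-count filter the control arm had 22 calls, against 2, and with the stricter filter the BC1215 arm had 345, against 642; the numbers of loci tested were 37239 and 16934. DESeq2 gave 1621 calls in the control arm, 2773 in the BC1215 arm, 39 between the arms and 3787 with both together, over 37175 loci tested. On the loci that passed the low-count filter it gave 1731, 2756, 40 and 3818 in the same order. Limma on log2(FPKM + 1) gave 1 in the control arm. Fitting only the groups compared gave 1 in the control arm and 997 in the BC1215 arm. A fold threshold of 2 left 783 with both arms together, by construction. Limma voom with library weights gave 5764 in the BC1215 arm and 4722 with both together, and library totals gave 247 in the BC1215 arm. Except for the fold threshold, the cause was not tested. The share of risen loci that were lower with BC1215 was 100% among the 2 loci called in the control arm, which were picked on the control libraries, against 36.1%.

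With each of the 6 post-LPS libraries left out in turn, the share of risen loci lower with BC1215 ran from 16.5% to 49.9%. With each library left out in turn, the counts ran from 0 to 421 in the control arm, 0 to 1825 in the BC1215 arm, 0 to 0 between the arms and 0 to 3187 with both together. Counts at an unadjusted p under 0.05 ran from 2316 to 5462, 2876 to 6073, 807 to 2584 and 4497 to 6940 in the same order. Of the adjusted counts, 3 of 12 stayed within 1.5 times in the control arm, 3 of 12 in the BC1215 arm and 2 of 12 with both together. Under the other settings, 8 of 14 stayed within 1.5 times in the control arm, 7 of 14 in the BC1215 arm and 8 of 13 with both together. Between the arms the count was 0 with each library left out and in 12 of 14 other settings. For the 4 named loci, 48 values stayed on their side of the threshold and 24 did not, and none changed direction.

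With the replicate block, which used the tables' library numbers, 0 loci were called in the control arm, the BC1215 arm, between the arms and with both together. The block joined libraries of the same number across all 3 groups. It left the pre-LPS libraries of higher numbers without a partner. Its counts therefore do not tell what a fit paired by lung would call. The numbers were not taken as pairs, because not every pair of deviations from the group means correlated above 0.1. Between control and pre-LPS libraries the correlations were 0.601, 0.082 and 0.269, and 2 of the 3 were best with their own number. None of the 3 pairs of BC1215 and pre-LPS libraries, at 0.065, -0.020 and -0.542, and none of the 3 between the arms was. Of the 6 post-LPS libraries, 3 correlated more closely with a pre-LPS library than with any library of their own group. Of all 11 other libraries, the closest to control libraries 0 and 1 was the pre-LPS library of the same number, at 0.976 and 0.981, and this held for 0 of the 3 BC1215 libraries. Pairs within a group also reached such values, with 0.983 for pre-LPS libraries 1 and 4 and 0.977 for BC1215 libraries 1 and 2. A correlation of this size does not by itself show a shared lung. If each lung had 1 treatment, a number could match in only 1 arm. The BC1215 values therefore do not speak against shared lungs in that arm. So some libraries may share a lung, which the labels do not tell.

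The gene lists fixed before the data were examined, with all their alternatives, were not run, because the files do not pair the loci with genes. A fit of only the groups compared does not differ from the reported fit for both arms together. Depth was 35898403 to 44740771 fragments per library, and how far depth rather than the spread between libraries limits the comparisons was not tested.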

Other observations

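The held-out ranking and the counts for other splits at an unadjusted threshold were tests chosen only after the calls were seen.

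Each library was left out in turn, the 500 highest-ranked rising and 500 falling loci were taken from the fit of the others, and the library was placed between the pre-LPS and post-LPS means of the others. By this measure 10 of 12 libraries lay nearer to their own side. The 6 pre-LPS libraries scored from -0.681 to -0.015 on the log2 scale, and 4 post-LPS libraries from 0.118 to 0.809. Control library 1, at -0.081, and BC1215 library 2, at -0.109, lay slightly nearer to the pre-LPS side, and leaving out either raised the count with both arms together, to 2646 and to 3187. The post-LPS libraries may thus share a response that differs in size between lungs or biopsies, a hypothesis found and tested on the same data. Between the arms, the same procedure placed 3 of 6 libraries nearer to their own arm.

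At an unadjusted p under 0.05, the real split gave 6005 loci with both arms together against at most 4662 in other splits, and 5147 in the BC1215 arm against at most 5104. In the control arm it gave 4423, and 3 of 84 splits gave as many, with 5071 the highest. Between the arms the real split gave 1683, and another split of the 6 libraries gave 3689.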
